A study of Rattus norvegicus with 8 samples.

How the data were processed

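RNA came from forebrain and hindbrain parts of rat embryos of both genotypes. Per the labels' protocols, heads were cut off at forelimb level and divided at the isthmus, total RNA was extracted with TRIzol, poly(A) RNA was purified and reverse-transcribed from an oligo(dT) primer carrying a T7 promoter, and biotin-labelled cRNA was hybridised to Affymetrix rat oligonucleotide arrays of the U34 set that were washed, stained and scanned by the manufacturer's manual. The authors deposited 1 intensity per probe set and array, on a linear scale. The software that made these values, its algorithm and its scaling are not given in the sources used here, and the table holds no detection calls. The deposited intensities included negative values, 18.3% to 22.3% of each array, with a lowest value of -9365 and a highest of 148131. The mean of each array after the lowest and highest 2% of its values were left out lay between 2504.1 and 2504.8, a range of 0.0297%, so the authors' scaling to a common mean was kept.

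The table held 8799 probe sets, of which 59 were controls of the array and were left out of tests. Gene names came from the platform annotation, which listed 7326 probe sets: 7018 with 1 symbol and 308 with several, from which no gene was named. The other 1473 had no symbol there. Entrez identifiers of 6994 matched a rat RefSeq gene table, and 0 symbols changed.

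Values below the pooled 25th percentile of all 8 arrays (45.9) were set to it and log2 was taken. A probe set was tested if it exceeded the pooled 40th percentile (255) on at least 2 arrays, which left 5881 probe sets, 4846 of them with 1 symbol and 3553 distinct symbols. All 8 arrays entered 1 linear model with 4 group means in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with an intensity trend, 4 residual degrees of freedom and 4.63 prior degrees of freedom. Contrasts were the genotype difference in forebrain, in hindbrain and averaged over both, the interaction, and forebrain minus hindbrain averaged over genotypes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Pax6 homozygous minus wild-type gives the sign of a genotype change. A fold that is not called at least is 2 to the power of the log2 change, so for dim probe sets it depends on the floor. Because values at the floor have no order, dim levels were also set against a noise level, the size of the 5th percentile of each array's intensities (243 to 619.8). Where no array on the dim side exceeded its noise level, the difference is given as at least N-fold: the mean log2 value of the bright side, each array at no less than its noise level, against that of the dim side with each array at the higher of its noise level and its own value. Group values are means ± SD of the intensities as deposited, and ± beside a log2 change is limma's standard error.

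The comparisons, the model, the threshold, 25 gene lists of brain regions, cell types, tissues in the dissections and pathways, the rule for named genes and most of the alternative settings were fixed before the data were examined. The rule took, for forebrain, hindbrain and region, the 12 genes in each direction with the largest fold among those past the threshold, filled to 12 with the smallest p among genes whose arrays did not overlap, the 4 members of each list with the smallest p, and Pax6 with its known or proposed targets. For the interaction it took the 6 genes with the smallest p in each direction. The same rule was later applied to the contrast over both regions, and lists were later tested in the interaction, neither of which was planned. Lists were tested with limma's camera with an inter-gene correlation of 0.01, with 1 probe set per gene, the brightest of those tested, and adjustment over all lists of a contrast. The same test with a correlation estimated from the residuals was an alternative. With an estimate camera takes p-values from the 4 residual degrees of freedom, and with the preset value from far more. The estimated version therefore has little power here. The count of list members past the threshold is given over all probe sets tested and adjusted over the list alone.

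The pipeline was tested on simulated data, with values drawn around the mean of each probe set with variances from the fitted prior and no group difference, and changes then added to 200 of 5881 probe sets in the Pax6 homozygous forebrain, 2 arrays against 2. It recovered 30% of 50 probe sets changed by 1 on the log2 scale, 54% of 50 changed by 2, 80% of 50 changed by 3 and 80% of 50 changed by 4, with 7 false calls. The simulated noise was independent between arrays, and no floor was applied to the simulated values. These rates therefore need not hold for the real arrays. A simulated list of 20 genes shifted by 0.7 on the log2 scale, among 3553 genes, was found by camera, and an unshifted list of 20 was not. The simulated genes were independent of each other, so this does not check how camera handles correlated genes. With 1 unshifted list it gives no rate of false calls. The alternatives were quantile normalization, equal trimmed means, an offset in place of the floor, no filter and a stricter filter, no intensity trend, the replicate number of the labels as a block over all arrays or within each region, each array left out in turn, a threshold of 0.10, the arrays of 1 region alone, a count of differences of 2-fold or more with no test, and the wild-type arrays alone for region. When an array was left out, the remaining array of its group was taken to vary like the other groups. Counts of alternatives in which a call held use the threshold of 0.05 and leave out that of 0.10. A floor at the pooled median (497) was added after seeing how many values were negative. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).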

Results

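Transcript levels were measured in E12.5 rat embryos that the labels call wild-type or Pax6 homozygous. Pax6 is a paired-domain transcription factor required for development of the eye, the nose and the forebrain, and the series was made to find genes that act downstream of it. The head was divided at the isthmus, so the forebrain part also held the midbrain and the primordia of eye and nose, and the hindbrain part also held the pharyngeal arches. The hindbrain part ran back to the cut at forelimb level, so it can also hold tissue caudal to the hindbrain. Each of the 4 combinations of genotype and region was hybridised to 2 arrays, 8 in all, and this number limits the precision of every value. Log2 values of the 2 arrays of a group correlated across probe sets with r between 0.899 and 0.947. Nothing in the sources used here says that the arrays of a group came from separate litters or animals, so p-values measure only the spread between these arrays, which can be technical.

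Pax6 itself was read by 1 probe set (S74393_s_at). In forebrain its intensity was 1197 and 636 on the wild-type arrays and 1243 and 927 on the Pax6 homozygous arrays. In hindbrain it was 827 and 531 on the wild-type arrays and 1194 and 1111 on the Pax6 homozygous arrays. The log2 difference, Pax6 homozygous minus wild-type, was 0.30 ± 0.42 (SE) in forebrain (adjusted p = 1) and 0.80 ± 0.42 in hindbrain (adjusted p = 0.989). The labels name neither the allele nor the part of the transcript that the probe set covers, so these levels check nothing about the genotype labels.

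In the forebrain part, Fabp7 (U02096_at), the brain fatty acid binding protein made by radial glia and neural progenitors, was 7.02-fold lower in the Pax6 homozygous group. Its intensity was 3526 ± 578 in wild-type and 499.9 ± 40.1 in Pax6 homozygous forebrain (mean ± SD, n = 2 arrays each), and both Pax6 homozygous arrays lay below both wild-type arrays. The log2 change was -2.81 ± 0.23 (SE, adjusted p = 0.00577). Fabp7 was the 1 probe set of 5881 that passed the test in forebrain, and no probe set passed as higher. An unadjusted p under 0.05 was reached by 172 probe sets, against 294 if p-values were uniform. Deviations of arrays with the same replicate number correlated (r from 0.275 to 0.465), and the model counts them as spread. A count under 294 therefore does not show that genotype effects are absent. The call ended without Pax6 homozygous forebrain replicate 1 (adjusted p = 0.0668) or replicate 2 (adjusted p = 0.0504), without a filter on dim probe sets (0.0613), without an intensity trend in the variance (0.0756) and with the 4 forebrain arrays alone (1). The number of probe sets past the threshold was 5 without wild-type forebrain replicate 1, 3 without wild-type forebrain replicate 2 and 0 without Pax6 homozygous forebrain replicate 1.

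Among lens genes, Cryaa (U47921_s_at), alpha-A crystallin of the lens, had an intensity of 5087 ± 237 in wild-type and 993 ± 438 in Pax6 homozygous forebrain (log2 change -2.43 ± 0.37), close to its level in wild-type hindbrain (878 ± 199). It did not pass over all probe sets (adjusted p = 0.248) but passed adjusted over the list alone (adjusted p = 0.00139). Crybb3, a beta crystallin, was at 2009.6 ± 326 in wild-type forebrain and 312 ± 221 in Pax6 homozygous forebrain, where no array rose above its noise level. The fold was at least 5.15 (adjusted p = 0.016 adjusted over the list alone, 1 over all probe sets). Of 11 lens genes measured, 9 had a negative log2 change, 0 passed over all probe sets and 2 passed adjusted over the list alone. As a list they were shifted down in the camera test (adjusted p = 0.013), but did not pass with an estimated correlation (adjusted p = 0.329).

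Aldh1a1 (AF001898_at), a retinaldehyde dehydrogenase that makes retinoic acid, was at 4789.6 ± 404 in wild-type and 1577 ± 452 in Pax6 homozygous forebrain (log2 change -1.63 ± 0.31, adjusted p = 0.404 over all probe sets and 0.00605 adjusted over the list alone). Cyp26b1, which breaks retinoic acid down, was at 624 ± 12.4 in wild-type forebrain and 252 ± 389 in Pax6 homozygous forebrain, where 1 of 2 arrays lay above noise. Of 11 retinoid pathway genes measured, 8 had a negative change and 1 passed adjusted over the list alone. The list was shifted down (adjusted p = 0.0302), but its adjusted p = 0.57 with an estimated correlation, and its adjusted p = 0.0696 after quantile normalization.

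Among 20 genes of neural progenitors and radial glia, 14 had a negative change and Fabp7 alone passed, over all probe sets and adjusted over the list alone. Id3, an inhibitor of basic helix-loop-helix factors, had a log2 change of -0.88 ± 0.31, and Cspg5, a neural proteoglycan, of -0.74 ± 0.32, neither of which passed. The list was shifted down (adjusted p = 0.00133), but with an adjusted p = 0.329 with an estimated correlation. The 5 measured genes of the list of known or proposed Pax6 targets gave an adjusted p = 0.0213 for a shift down, and an adjusted p = 0.329 with an estimated correlation. Of the 5, 3 had a negative and 2 a positive change. Fabp7 passed in both ways, 0 others did, and Sox11 and L1cam had log2 changes of -0.13 ± 0.29 and 1.65 ± 1.39. Fabp7 entered the target list from general knowledge of Pax6 that can rest on these same samples, so its direction there is not independent evidence. Fabp7 and Pax6 are also members of the progenitor list, so the results of these 2 lists are not independent of each other.

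The lists of blood and macrophage genes were also shifted down, in the same arrays as the lens, retinoid and progenitor groups. Of 11 blood genes measured, 9 had a negative change, 0 passed over all probe sets and 2 passed adjusted over the list alone (list adjusted p = 0.000531, and adjusted p = 0.329 with an estimated correlation). These were Hbg1 (46735 ± 3350.1 in wild-type and 34244 ± 2597 in Pax6 homozygous forebrain, log2 change -0.45 ± 0.12) and Hbb-b1 (log2 change -0.78 ± 0.22), globin chains whose probe sets share sequence within the family. Of 8 macrophage and microglia genes, 7 had a negative change and 0 passed in either way. Ptprc, the leukocyte common antigen, had no Pax6 homozygous forebrain array above noise. The list gave an adjusted p = 0.0302 for a shift down, and an adjusted p = 0.329 with an estimated correlation.

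The list of cell adhesion and axon guidance genes was shifted up (adjusted p = 0.0302), but its adjusted p = 0.779 with an estimated correlation, and its adjusted p = 0.0765 with the mean of all probe sets of a gene. Of its 20 measured genes 16 had a positive change and 0 passed in either way. Cdh2, N-cadherin, was at 2485 ± 147 in wild-type and 3319.6 ± 384 in Pax6 homozygous forebrain (log2 change 0.41 ± 0.24), and the guidance receptor Epha7 at 738 ± 189.9 and 1051 ± 3.25 (log2 change 0.53 ± 0.35). The dorsal and ventral telencephalon lists did not pass (list adjusted p = 0.941 and 0.344). In the dorsal list 6 of 7 genes had a negative change. The remaining gene, Neurod2, passed as higher adjusted over the list alone (log2 change 3.07 ± 0.64, adjusted p = 0.00732, and 0.615 over all probe sets). It was dim, with both wild-type arrays at the floor and a fold of at least 1.28. Outside the lists, the lowest adjusted p after Fabp7 belonged to a probe set of Marcks (rc_AA859896_at), a substrate of protein kinase C, at 4487 ± 579 and 1314 ± 157 (log2 change -1.77 ± 0.22, adjusted p = 0.0918). The log2 changes of its other probe sets were -0.30, -0.28 and -0.60. Cdh22, a brain cadherin, was at 7368 ± 874 and 12084 ± 864 (log2 change 0.72 ± 0.17, adjusted p = 0.902), and the endoplasmic reticulum protein Erp29 at 9042 ± 1472 and 4382 ± 578 (log2 change -1.04 ± 0.19, adjusted p = 0.404). Of the 24 genes named by rule for this comparison, 8 had no array above noise on their dim side.

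**Figure D1:**
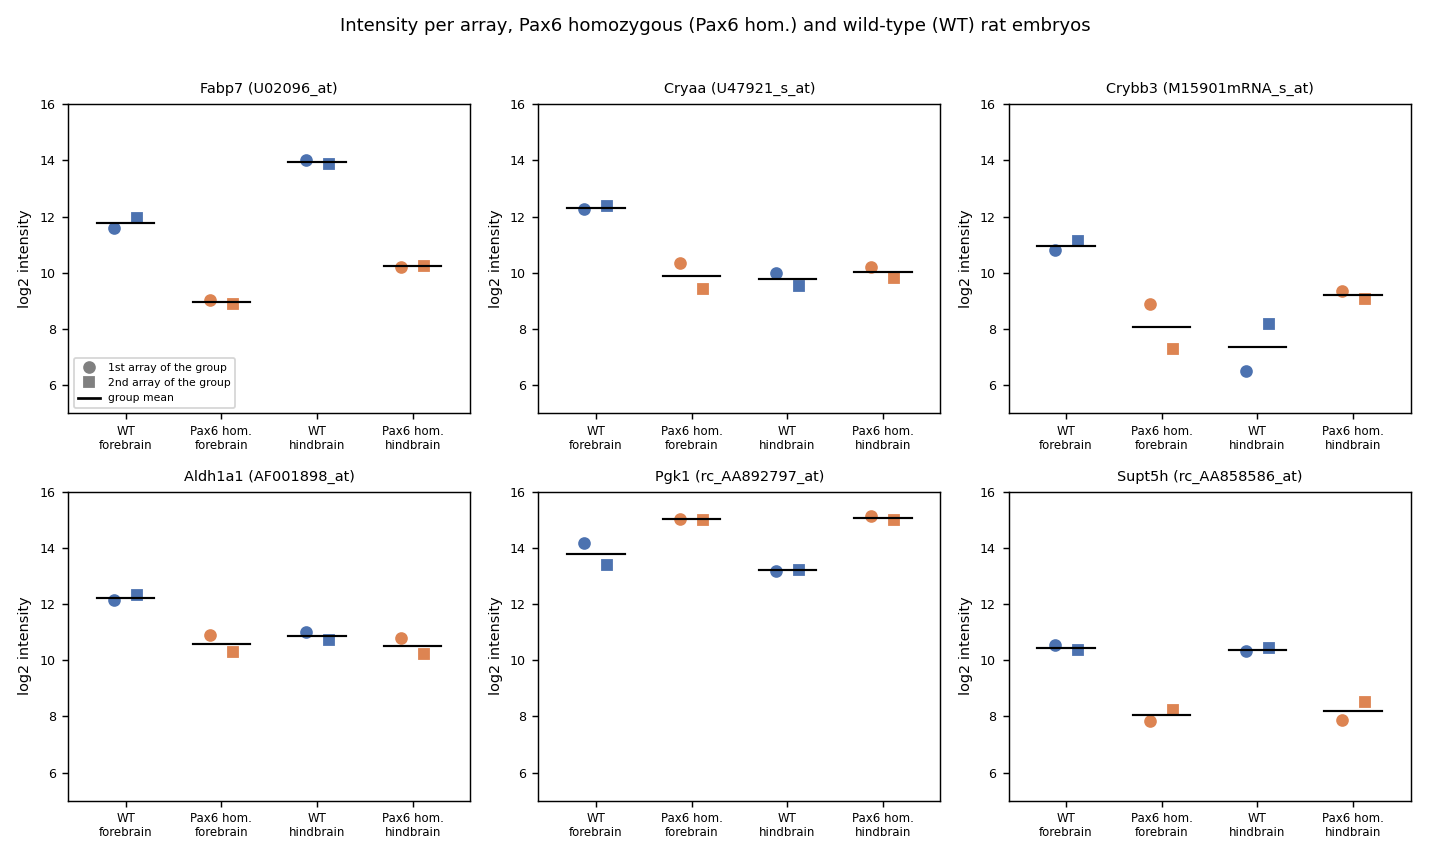
Log2 intensity, after values under the floor of 45.9 were set to it, of 6 probe sets on each of the 8 arrays; circles and squares are the 2 arrays of a group and lines are group means. Fabp7 lay lower in both Pax6 homozygous groups, Cryaa and Crybb3 were highest in wild-type forebrain, and the Pgk1 and Supt5h probe sets differed by genotype in both regions.

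In the hindbrain part, Fabp7 was 13.2-fold lower in the Pax6 homozygous group, at 15839.6 ± 1031 in wild-type and 1197 ± 10.3 in Pax6 homozygous hindbrain (n = 2 arrays each). The log2 change was -3.72 ± 0.23 (adjusted p = 0.000558), and both Pax6 homozygous arrays lay below both wild-type arrays. It was again the 1 probe set of 5881 past the threshold, with 264 at an unadjusted p under 0.05 against 294 with uniform p-values. The Fabp7 call held in all 18 alternatives tried. The number of probe sets past the threshold was 2 without wild-type forebrain replicate 1, wild-type forebrain replicate 2, wild-type hindbrain replicate 1 or Pax6 homozygous hindbrain replicate 2, and 3 without wild-type hindbrain replicate 2.

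Genes of neuronal differentiation were shifted down in the Pax6 homozygous hindbrain as a list (median log2 change -0.24 over 23 genes, adjusted p = 0.00465). The list did not pass with an estimated correlation (adjusted p = 0.541). Of the 23, 16 had a negative change and 0 passed over all probe sets or adjusted over the list alone. Ina, the neuronal intermediate filament alpha-internexin, was at 18277 ± 523 in wild-type and 9982 ± 486 in Pax6 homozygous hindbrain (M73049_at, log2 change -0.87 ± 0.20, adjusted p = 0.0512 adjusted over the list alone and 0.894 over all probe sets). A further Ina probe set gave -0.76 ± 0.17. Gap43, a growth cone protein, was at 9884 ± 2133 and 5970.2 ± 328 (log2 change -0.71 ± 0.19, adjusted p = 0.989), and Syp, synaptophysin of synaptic vesicles, at 2011 ± 175 and 1040.2 ± 24 (log2 change -0.95 ± 0.44). The blood list, shifted in forebrain, had an adjusted p = 0.0852 in hindbrain, with a negative change in 8 of 11 genes, and an adjusted p = 0.541 with an estimated correlation.

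Further genes of the hindbrain comparison did not pass the test. Sfpq, a splicing factor, was at 6204 ± 139 in wild-type and 12312 ± 1084 in Pax6 homozygous hindbrain (log2 change 0.99 ± 0.19, adjusted p = 0.575), and Cabin1, a calcineurin-binding protein, at 4379 ± 35.5 and 7879 ± 765 (log2 change 0.84 ± 0.17, adjusted p = 0.575). Ecel1, a neuronal endopeptidase, was at 1414 ± 102 and 319 ± 28.1 (log2 change -2.15 ± 0.50, adjusted p = 0.894, but 0.00241 with the floor at the pooled median), and Psat1, an enzyme of serine synthesis, at 8137 ± 855 and 4936 ± 434 (log2 change -0.72 ± 0.17). At the pooled median floor both Pax6 homozygous hindbrain values of Ecel1 became equal, and its standard error fell to 0.0505. That pass therefore rests at least in part on spread that the floor removed. Slc18a3, the vesicular acetylcholine transporter of cholinergic neurons, was at 1849 ± 539 and 314 ± 963, with 1 of 2 Pax6 homozygous arrays above noise, and passed only without Pax6 homozygous hindbrain replicate 2 (adjusted p = 0.0473). Of the 24 genes named by rule for hindbrain, 9 had no array above noise on their dim side.

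Over both regions, with 4 arrays of each genotype, 2 probe sets passed. Fabp7 was 9.63-fold lower (log2 change -3.27 ± 0.16, adjusted p = 9.06e-05), a call that held in all 17 alternatives. A probe set of Pgk1 (rc_AA892797_at), phosphoglycerate kinase of glycolysis, was higher in the Pax6 homozygous groups, at 14534 ± 5369 against 33114 ± 792 in forebrain and at 9389.8 ± 136 against 34160.4 ± 2200.3 in hindbrain (log2 change over both regions 1.55 ± 0.16, adjusted p = 0.0171). The other tested Pgk1 probe sets changed by a mean of 0.14 ± 0.12 on the log2 scale. The next probe set, of the transcription elongation factor gene Supt5h (rc_AA858586_at), was at 1398 ± 132 against 264 ± 54 in forebrain and 1325 ± 67.4 against 299 ± 91.9 in hindbrain, with 1 of 2 Pax6 homozygous arrays above noise in each (log2 change over both regions -2.30 ± 0.29, adjusted p = 0.0646), while the other tested Supt5h probe sets changed by a mean of 0.37 ± 0.16. The Supt5h probe set passed over both regions in 2 of 17 alternatives at the threshold of 0.05, the replicate number as a block over all arrays and the floor at the pooled median. With the floor at the pooled median it passed over both regions (log2 change -1.45, adjusted p = 0.00498), in forebrain (adjusted p = 0.0458) and in hindbrain (adjusted p = 0.0195). At that floor all Pax6 homozygous values of this probe set became equal, so these passes rest at least in part on spread that the floor removed. Erp29 and the nuclear protein gene Ptms had log2 changes of -0.74 ± 0.14 (adjusted p = 0.392) and -0.63 ± 0.12 (adjusted p = 0.427). An unadjusted p under 0.05 was reached by 295 probe sets, against 294 with uniform p-values. The Pgk1 call ended without either Pax6 homozygous forebrain array or any of the 4 hindbrain arrays (adjusted p from 0.0856 to 0.217), and also without a filter (0.135), without an intensity trend (0.189) and with the floor at the pooled median (0.144). The number past the threshold was 5 without wild-type forebrain replicate 1, and 1 without either Pax6 homozygous forebrain array, either Pax6 homozygous hindbrain array or wild-type hindbrain replicate 2.

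Whether the genotype effect differed between regions was tested as an interaction. With limma, 0 probe sets passed, 112 had an unadjusted p under 0.05 where uniform p-values would give 294, and the smallest adjusted p was 0.9995. Fabp7, chosen here after its values were seen, had an interaction of 0.91 ± 0.33 on the log2 scale, forebrain minus hindbrain. Cryaa, above noise on all 8 arrays, had an interaction of -2.68 ± 0.52, and the Marcks probe set of -1.69 ± 0.32. The interactions of Crybb3 and Ecel1 rest in part on values under the noise level. No Pax6 homozygous forebrain array for Crybb3 and no wild-type forebrain array for Ecel1 rose above noise. That of Crybb3 was -4.76 ± 1.00, and -2.26 with the floor at the pooled median. That of Ecel1 was 4.21 ± 0.71, and 1.51 with the floor at the pooled median, where it passed (adjusted p = 0.00944), as it did without an intensity trend (adjusted p = 0.0186). At that floor every Ecel1 array outside wild-type hindbrain took the same value. The pass there rests at least in part on spread that the floor removed. The count was 1 without wild-type forebrain replicate 1 or wild-type hindbrain replicate 1, 13 without a filter, 8 with the floor at the pooled median and 4 without an intensity trend.

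**Figure D2:**
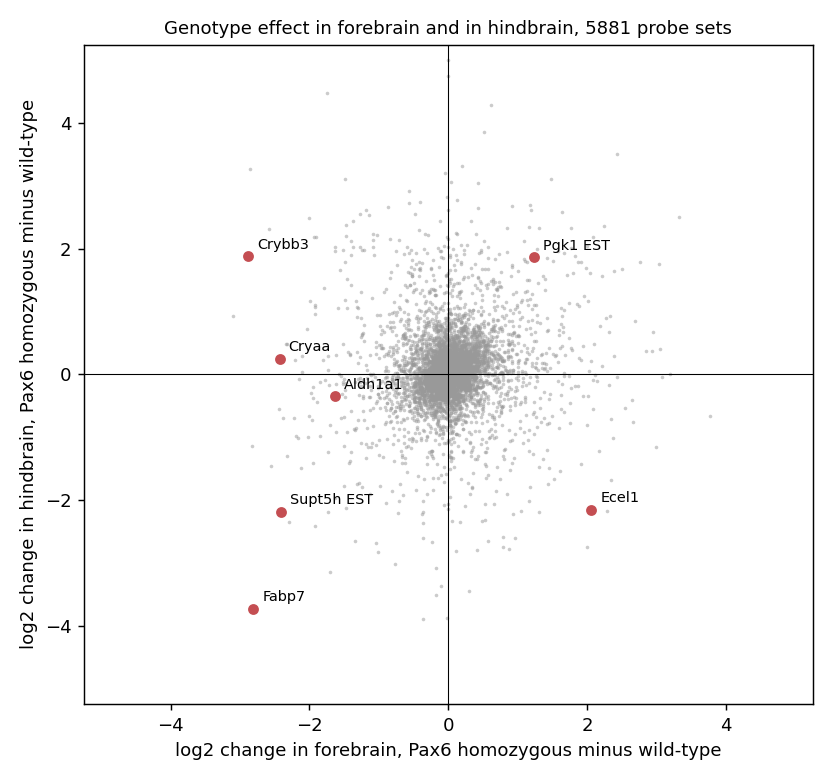
Genotype effect in hindbrain (y axis) against that in forebrain (x axis), each as the log2 change of Pax6 homozygous minus wild-type, with 1 grey point for each of 5881 probe sets and named probe sets in red. Fabp7 lay at -2.81 and -3.72, and Cryaa at -2.43 in forebrain.

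Forebrain and hindbrain parts differed far more than the genotypes did. Over both genotypes 89 probe sets passed, 17 higher in forebrain (14 genes) and 72 higher in hindbrain (45 genes), and 476 had an unadjusted p under 0.05 against 294 expected. Alx1, a homeobox gene of head mesenchyme, was at 5924 ± 1741 in wild-type forebrain and above noise on no hindbrain array, at least 17.2-fold higher (adjusted p = 3.76e-05). Nkx2-1, of the ventral forebrain, was at 4144 ± 188 in wild-type forebrain and 443 ± 304 in wild-type hindbrain (log2 difference over both genotypes 4.11 ± 0.32, adjusted p = 0.000277), and Lhx2, a LIM homeobox gene of forebrain and eye, at 8482 ± 296 and 1660.0 ± 199 (log2 difference 2.39 ± 0.14, adjusted p = 4.43e-05). Dlk1, a Notch-like membrane protein, at 16129 ± 1014 and 4038 ± 699.8, and Dlx5, of ventral forebrain and nasal placode, at 1024 ± 40.8 and 247 ± 30.2, also passed as higher in forebrain (adjusted p = 0.000101 and 0.0286). The calls of Alx1, Nkx2-1, Lhx2 and Dlk1 held in all 18 alternatives. The call of Dlx5 held in 8 of 18 and in 0 of the 8 with an array left out, and its log2 difference of 1.68 became 0.78 with the floor at the pooled median. The count was 41 without Pax6 homozygous hindbrain replicate 1, 52 without wild-type hindbrain replicate 2, 37 without Pax6 homozygous hindbrain replicate 2 and 46 for the wild-type arrays alone. Other genes of the forebrain lists went the other way. Values were higher in hindbrain for 6 of 7 dorsal telencephalon genes (list adjusted p = 0.0527), with Neurod1 and Neurod2 past the threshold. They were also higher there for 4 of 7 ventral telencephalon and GABAergic genes (list adjusted p = 0.833), with Sst past the threshold. The same held for 4 of 4 eye and pigment epithelium genes, Ttr among them (list adjusted p = 0.000859, and 0.171 with an estimated correlation).

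Of the Hox genes, Hoxa5 was at 2382 ± 483 in wild-type hindbrain and above noise on no forebrain array, at least 5.46-fold higher (adjusted p = 7.8e-05), and Hoxd3 was at least 2.14-fold higher (adjusted p = 0.00869). These calls held in 18 and 13 of 18 alternatives. These were the 2 of 3 measured Hox genes that passed, both higher in hindbrain, over all probe sets and adjusted over the list alone (list adjusted p = 0.00113, and adjusted p = 0.11 with an estimated correlation). The remaining member, Hoxc4, was above noise on no array. Ttr, transthyretin of choroid plexus, was at 9700.1 ± 1343 in wild-type hindbrain and above noise on no forebrain array, at least 18.9-fold higher (adjusted p = 3.76e-05). Of 5 genes of hindbrain patterning measured, 5 had higher values in hindbrain, 0 passed over all probe sets and 3 passed adjusted over the list alone (list adjusted p = 0.000848, and adjusted p = 0.11 with an estimated correlation). Fabp7, too, was higher in hindbrain over both genotypes (log2 difference -1.72 ± 0.16, adjusted p = 0.000854).

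Of the neuronal genes, Nefl, the light neurofilament, was at 2077 ± 264 in wild-type forebrain and 16087 ± 3528 in wild-type hindbrain (log2 difference -2.61 ± 0.16, adjusted p = 6.31e-05), and Nefm, the medium neurofilament, at 2966 ± 107 and 21578 ± 933 (log2 difference -2.78 ± 0.18, adjusted p = 7.8e-05). Of 23 genes of neuronal differentiation, 21 had higher values in hindbrain, 5 passed over all probe sets and 11 adjusted over the list alone, each higher in hindbrain (list adjusted p = 1.24e-12, and adjusted p = 0.0649 with an estimated correlation). Of 14 genes of neural crest and peripheral neurons, 2 passed over all probe sets and 7 adjusted over the list alone (list adjusted p = 7.63e-08, and adjusted p = 0.0649 with an estimated correlation). The first 2 were Prph, the peripheral neuron filament, at least 3.599-fold higher in hindbrain (adjusted p = 0.00576), and Ngfr, the neurotrophin receptor of crest cells (log2 difference -1.22 ± 0.15, adjusted p = 0.00359). Their calls held in 14 and 18 of 18 alternatives. Isl1, a homeobox gene of motor and sensory neurons, was at 371 ± 373 in wild-type forebrain and 2951 ± 204 in wild-type hindbrain and did not pass (adjusted p = 0.0614). It passed in 5 of 18 alternatives, among them without wild-type forebrain replicate 1 (adjusted p = 0.0158) or replicate 2 (0.00152), with an offset in place of the floor (0.0441) and with the floor at the pooled median (0.0313).

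In the list of muscle genes, Actc1, cardiac actin, was at 15613 ± 1425 in wild-type hindbrain and above noise on no forebrain array, at least 37.4-fold higher (adjusted p = 7.35e-07). Tnnc2, fast skeletal troponin C, was at least 3.15-fold higher (adjusted p = 0.000523) and Acta1, skeletal actin, at least 5.16-fold (adjusted p = 0.0103). The calls of Actc1 and Tnnc2 held in all 18 alternatives, and that of Acta1 in 11. Of 23 muscle genes measured, 19 had higher values in hindbrain, 4 passed over all probe sets and 9 adjusted over the list alone (list adjusted p = 6.14e-10, and adjusted p = 0.11 with an estimated correlation). The list of epithelial genes was shifted to hindbrain as well (10 of 11 with higher values in hindbrain, list adjusted p = 0.00282, and adjusted p = 0.114 with an estimated correlation), with Krt19, a simple epithelial keratin, at least 2.04-fold higher (adjusted p = 0.0149, a call held in 10 of 18 alternatives), the 1 member that passed over all probe sets or adjusted over the list alone. Blood genes had higher values in forebrain in 11 of 11, with a median log2 difference of 0.22 and 0 past the threshold in either way (list adjusted p = 0.00282, and adjusted p = 0.135 with an estimated correlation). In all, 14 of 25 lists passed for region, and 0 did with an estimated correlation (adjusted p from 0.0649 to 0.302 for the 14).

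**Figure D3:**
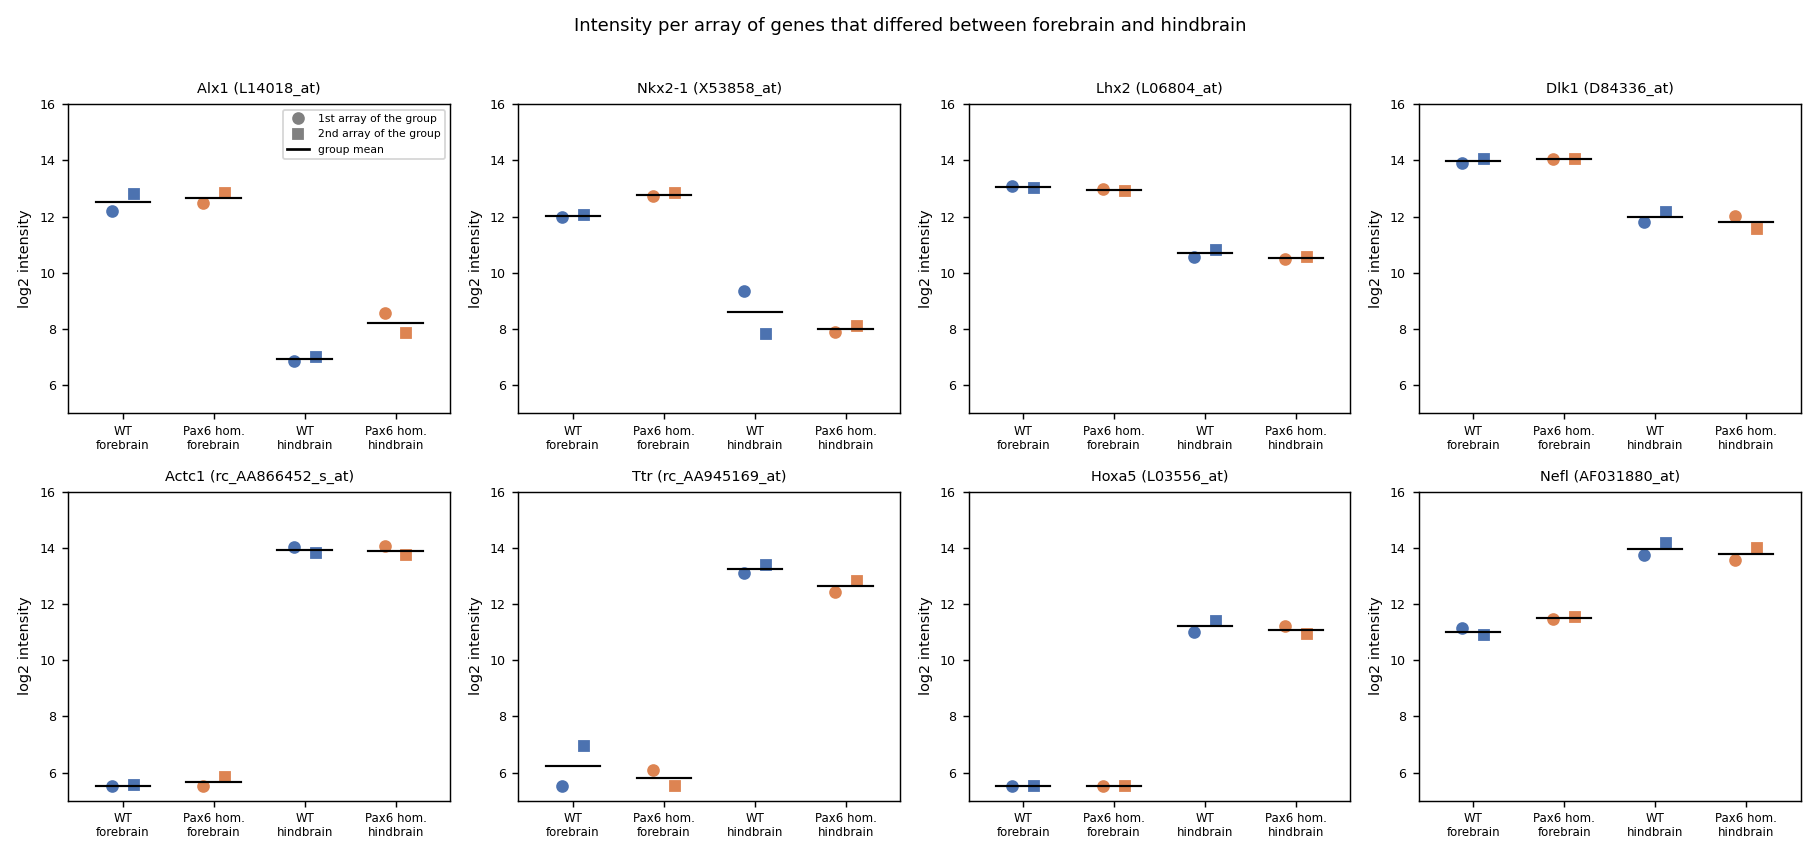
Log2 intensity, after values under the floor of 45.9 were set to it, of 8 probe sets on each of the 8 arrays; circles and squares are the 2 arrays of a group and lines are group means. Alx1, Nkx2-1, Lhx2 and Dlk1 were higher in forebrain, and Actc1, Ttr, Hoxa5 and Nefl in hindbrain, in both genotypes.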

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

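List tests of the interaction were not among the planned tests and were added after the files were examined, and the comparison of Pgk1 and Supt5h probe sets was written only after their change had been seen. Lens genes were picked out by tests of a difference in genotype effect between forebrain and hindbrain, which Cryaa and Crybb3 passed only adjusted over the list alone and which the lens list did not pass with an estimated correlation. Cryaa had an interaction of -2.68 ± 0.52 and Crybb3 of -4.76 ± 1.00 on the log2 scale, each with an adjusted p = 0.00629 adjusted over the list alone and 0.9995 over all probe sets. Part of the Crybb3 interaction came from hindbrain, where it was at 191 ± 143 in wild-type and 596 ± 84.2 in Pax6 homozygous arrays. Cryaa was above noise on all 8 arrays, whereas the Crybb3 value rests in part on values under the noise level. For Crybb3, no Pax6 homozygous forebrain array and 1 of 2 wild-type hindbrain arrays rose above noise. Its interaction was -2.26 with the floor at the pooled median. The lens list gave an adjusted p = 0.0455 for the interaction (9 of 11 genes negative), an adjusted p = 0.0724 after quantile normalization and an adjusted p = 0.709 with an estimated correlation. The list of ventral telencephalon and GABAergic genes gave an adjusted p = 0.0187, with a positive interaction in 6 of 7 genes, and an adjusted p = 0.709 with an estimated correlation. Among the 6, Gad1 (1.56) had no Pax6 homozygous hindbrain array above noise, and Nkx2-1 (1.37) had 1 of 2 in each hindbrain group. Isl1 (2.20), also in the motor neuron list, had 1 of 2 wild-type forebrain arrays above noise. This list result therefore rests in part on values under the noise level. Cell adhesion and axon guidance genes gave an adjusted p = 0.0187, with a positive interaction in 17 of 20, and an adjusted p = 0.709 with an estimated correlation.

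For the lens genes, a dissection that left out facial tissue in the mutant was tested. The mesenchyme and surface epithelium genes together had a median log2 change of 0.000906 in forebrain (43 genes, bootstrap 95% interval -0.102 to 0.105), which argues against a general loss of facial tissue on these arrays. The bootstrap drew genes, which were read on the same arrays and can move together. Its interval is therefore a spread between genes and does not measure differences between dissections. Loss of the eye primordium alone, by the mutation or by the dissection, was not separated by any test here. A failure of lens formation in Pax6 homozygous embryos therefore remains a hypothesis that was not tested.

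The Pgk1 probe set rc_AA892797_at and the Supt5h probe set rc_AA858586_at moved with genotype in both regions. A change of the whole gene would move the other probe sets of each gene alike, but their mean change was at most 0.0873 of that of the moving probe set, which argues against it. A variant inherited with the Pax6 locus would need the genes to lie on the Pax6 chromosome, and 0 of the 2 did as annotated, while a copy elsewhere in the genome was not tested. Among the 100 probe sets with the smallest p for genotype over both regions, 8% lay on the Pax6 chromosome against 7.22% of the others (one-sided Fisher's exact p = 0.437). The 95% interval of 3.52% to 15.2% does not exclude a doubled share of 14.4%, so linked variants stay open. No biological explanation was tested.

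For the lower neuronal differentiation genes in Pax6 homozygous hindbrain (median log2 change -0.24, bootstrap 95% interval -0.347 to -0.0932), a larger share of non-neural tissue would raise mesenchyme and muscle genes. Their median change was -0.0369 (55 genes, interval -0.0896 to -0.000828), so they did not rise as a set. The rise that such a share would give depends on how much of the part is neural, which was not measured. A small rise could be missed, so the explanation is not excluded. These intervals were drawn over genes and not over arrays. A cut that left out caudal hindbrain would lower Hox genes, but this test could not decide it. The median change of 0 over 3 genes (interval -0.129 to 0.407) was that of Hoxc4, which was at the floor in hindbrain and carries no value, and the others were Hoxa5 (-0.13) and Hoxd3 (0.41). Since both explanations stayed open and the list did not pass with an estimated correlation (adjusted p = 0.541), reduced neuronal differentiation was not separated from dissection.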

How the results depend on the processing

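Of the alternatives here, the floor at the pooled median was added after the values had been seen, because so many were negative, and the list tests of the interaction were added without a plan. The planned floor at the pooled 10th percentile could not give a value, because that percentile was negative. Over 113 gene results and 2012 alternatives, 1814 stayed the same, 167 were weaker, 23 were stronger and 8 reversed. Same means that the sign and the side of the threshold held, so a gene that never passed counts as the same. Weaker can arise only for results past the threshold in the main fit, so its share among those is larger than these counts show. Where a value moved, the cause was not tested. Signal over background limits the dim probe sets: 18.3% to 22.3% of intensities were negative. Changes of genes under the noise level rest on values not told apart from noise, or on the floor where values fell below it.

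The forebrain count of 1 became 3 with the floor at the pooled median, 0 without a filter, 0 without an intensity trend, 2 at a threshold of 0.10, 0 with the forebrain arrays alone and 0 to 5 with an array left out. The hindbrain count of 1 became 15, 22, 5, 2 and 2 in that order, and 1 to 3 with an array left out. Over both regions the count of 2 became 10 with the floor at the pooled median, 19 without a filter and 1 to 5 with an array left out. The interaction count of 0 became 8, 13 and 4 with that floor, without a filter and without a trend, and 0 to 1 with an array left out. The region count of 89 became 46 for the wild-type arrays alone and 37 to 82 with an array left out. At the floor of the pooled median many arrays take the same value, so small changes can pass, as Plcl1 did in hindbrain (log2 change 0.10). Without any test, 219 probe sets in forebrain and 339 in hindbrain differed 2-fold or more with no overlap. Groups did not overlap in 22.8% and 34.4% of probe sets, where chance gives 33.3% for independent arrays without ties. Values tied at the floor counted as overlap and arrays of the same number deviated together, so chance can give less than 33.3% here.

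With the replicate block the hindbrain count was 2 (Pgk1 joined, adjusted p = 0.0498), the count over both regions 3 (Supt5h joined, adjusted p = 0.0296), the region count 139, and 3 of the 7 forebrain lists passed, while those of Pax6 targets, retinoid pathway, adhesion and macrophages did not (adjusted p = 0.0554 each). Isl1 passed for region (adjusted p = 0.0263). The lens list did not pass for the interaction (adjusted p = 0.0738). With the replicate block within each region the region count was 46. The labels do not say what the number marks, and deviations of arrays with the same number correlated with r from 0.275 to 0.465 across probe sets. With an estimated correlation, 0 lists passed in forebrain (7 before), 0 in hindbrain (1 before) and 0 for region (14 before). A higher correlation does not account for every loss, since the 4 residual degrees of freedom used with an estimate also raise p. A list that did not pass there is therefore not shown to have shifted through correlated genes. The estimate was -0.041 for the forebrain progenitor list and -0.0395 for the neural crest list of region, both under the preset 0.01. Their adjusted p in camera still rose from 0.00133 to 0.329 and from 7.63e-08 to 0.0649. Other lists had estimates above the preset, such as 0.0746 for lens genes. With the mean of all probe sets of a gene, 2 lists passed in hindbrain, ventral telencephalon and GABAergic genes having joined (camera adjusted p = 0.0456). The hypoxia and glycolysis list joined in forebrain (0.00384, against 0.278 in the main test), and neuronal differentiation in the interaction (0.00553, against 0.142). For region the mesenchyme list joined (0.042), while those of progenitors (0.0591) and cell cycle (0.0718) no longer passed.

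With an array left out, the forebrain log2 change ran from -0.59 to 0.33 for Sox11, from -0.16 to 0.76 for Pax6 and from -1.004 to 4.31 for L1cam, which was -0.0645 with the floor at the pooled median. The hindbrain change ran from -0.32 to 0.0104 for Sox11 and from -0.13 to 1.47 for L1cam. The region difference of Pax6 ran from -0.0809 to 0.38, and was -0.01 without wild-type hindbrain replicate 2.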

Other observations

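The division of the arrays into sets of 4 was planned before its result was seen, and the correlation of genotype effects was added without a plan. Igfbp2, an insulin-like growth factor binding protein, was at 22041 ± 3072 in wild-type forebrain and 8319 ± 1310.5 in wild-type hindbrain (mean intensity ± SD, n = 2, log2 difference over both genotypes 1.29 ± 0.12, adjusted p = 0.000848), a call that held in all 18 alternatives. Igf2, a growth factor of the embryo, had a log2 difference of -0.69 ± 0.12 (adjusted p = 0.0258) and the binding protein Igfbp3 of -1.13 ± 0.20 (adjusted p = 0.0292), both higher in hindbrain. Their calls held in only 8 and 6 of 18 alternatives, and in 2 and 0 of the 8 with an array left out.

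Sst, somatostatin, was at 18978 ± 3793 in wild-type hindbrain and 3087 ± 1349 in wild-type forebrain (log2 difference -2.46 ± 0.22, adjusted p = 0.00066), a call that held in all 18 alternatives. Calb2, the calcium-binding protein calretinin, was also higher in hindbrain (log2 difference -1.50 ± 0.20, adjusted p = 0.00687, held in 14 of 18), as was the proneural factor gene Neurod1 (log2 difference -0.93 ± 0.14, adjusted p = 0.0137, held in 10 of 18). Tac1, the precursor of substance P, passed as higher in forebrain (log2 difference 2.10 ± 0.34, adjusted p = 0.0183), but held in 8 of 18 alternatives and in 2 of the 8 with an array left out.

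Across 5881 probe sets, which are not independent, genotype effects in forebrain and hindbrain correlated with Spearman's rho = 0.166, and 57.6% had the same sign, against rho = 0.253 and 59.9% for the 4244 probe sets with a mean above the pooled median. The 8 arrays were also divided into 4 and 4 in every way that could be fitted, with the other factor in the model. For genotype 3 probe sets passed in this model, and 2 of 34 splits had as many, counting the real one, with a highest other count of 371. For region 109 passed, and 2 of 34 splits had as many, with a highest other count of 348. In both cases that higher count came from the split by replicate number, which points to a structure of the samples, while every remaining split gave at most 2 probe sets for genotype and 1 for region. In the model of 4 group means with the replicate number as a block, the counts were 3 and 139. With 2 of 34 splits as large, the share set beforehand was not reached, so this test alone does not exclude chance for either count.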
